A study of Solanum lycopersicum with 8 samples.

How the data were processed

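RNA from the peel of mature green fruit of 4 tomato genotypes, 2 biological replicates each, was hybridised to 8 Affymetrix Tomato Genome Arrays after biotin labelling, 1 array per sample. Plants were grown in winter in a heated greenhouse with a minimum of 12 °C. Fruit collected at later stages was not analysed here. The table used holds 1 intensity per probe set and array, deposited by the authors on a linear scale, with no log transform. The submitters' processing notes name GCRMA without a version; what the intensities are relative to is not given in the sources used here. Array medians and quartiles differed between arrays, so the deposited intensities had not been made equal in distribution. For this reason, and before any test was run, the 8 arrays were quantile-normalized, values under 1 were set to 1, and log2 was taken. The design fixed before the data were examined had used the deposited values as they were; these are given beside each count as the alternative.

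The table has 10209 probe sets, of which 171 controls were left out. A probe set was tested if its log2 value was at least 4 in at least 2 arrays, a rule blind to genotype; 545 failed and 9493 were tested. The platform annotation gave a gene symbol to 909 probe sets, and 849 of those, for 754 genes, were tested; 885 were matched by gene identifier to a current gene table. The planned test of the chromosomes of changed genes needed 80% of tested probe sets to be placed and was not run, since 8.94% carried a gene name. Chromosomal positions of genes were not used here.

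Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (4 residual and 1.77 prior degrees of freedom), so that all genotypes share 1 estimate of the spread. The 6 comparisons were each mutant against wild type, the double mutant against each single mutant, and the interaction. Tests were two-sided, p values were adjusted by Benjamini and Hochberg over the probe sets tested, and the threshold was an adjusted p of 0.05. Where a genotype was near background, a fold is given as at least the value obtained with intensities floored at 16. Signals near the top of the range can be compressed, so changes of bright genes are given as measured. Errors are SD between 2 replicates for levels and SE from limma for changes. Groups of 2 arrays allow no count of regrouped samples and no test for single outlying samples.

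Of 22 gene lists fixed before the data were examined, those with at least 3 tested genes were tested, 14 in all, with 1 probe set per gene, so other probe sets of a gene can differ from the one counted. Lists were tested by camera with a preset correlation of 0.01 and, beside it, an estimated correlation, and by fry, adjusted over all lists and comparisons. Camera asks whether a list moves against the other genes, fry whether it moves at all; fry called 8, 10, 8, 6, 11 and 8 of the 14 lists in the order of the comparisons above, where camera called 2, 5, 0, 3, 4 and 4. All 18 list shifts called with the preset correlation were lost with the estimated one. The estimate was 0.07, 0.13 and 0.16 for the carotenoid, defence and ripening lists. For the heat shock, cold and drought and photosynthesis lists it was -0.12, -0.11 and -0.004, below the preset. A higher correlation between members therefore does not account for the loss in those last lists. With an estimated correlation camera uses only the 4 residual degrees of freedom, and with the preset many more. This raises p even where the estimate lies below the preset. A shift lost with the estimated correlation is thus not by itself evidence of correlated members. The lists cover anthocyanin branch, general flavonoid, phenylpropanoid and carotenoid genes, MYB-bHLH-WD40 regulators, ripening and ethylene, cell wall, auxin, gibberellin, sugar and starch, light signalling, photosynthesis, heat shock, cold and drought, defence and wound, ribosomal protein, histone and reference genes, and markers of cuticle and epidermis, vascular tissue, seed and trichomes. Members were found by symbol, so each list holds only the named part of its pathway. Named genes are the flavonoid, anthocyanin and regulator genes, up to 10 rises and 10 falls by size of change among called genes with an informative symbol, the 3 members with the lowest p of every other list, and the candidate genes of both loci where a probe set is present. A symbol made of LOC and a number counted as informative only where the annotation gave a synonym. A few genes named outside this rule, all from the set changed in all 3 mutants, were chosen after their values were seen.

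The fit was tested on simulated data with 50 probe sets changed at each of 4 sizes. It recovered 2 changes of 0.5, 29 of 1, 47 of 2 and all 50 of 3 on the log2 scale; 11 of 139 calls were false, and none was made in a contrast left unchanged. A raised list of 14 genes was found by camera with either correlation, and an unchanged list was not. All simulations here gave a probe set the same spread in every genotype. In the data the median SD between replicates was 0.086 in the wild type and 0.135 in the Aft mutant. It was 0.175 in the atv mutant and 0.090 in the double mutant. The simulations therefore cannot show how the shared spread acts where genotypes differ in spread. Alternatives covered the filter, an intensity trend in the moderation, the deposited scale, a replicate block, fits to 2 groups, probe set types, single arrays left out, all probe sets of a list, and the estimated correlation. Equal array medians, a floor of 16 and a fit without the atv mutant arrays were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.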

Results

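Transcripts were measured in the peel of mature green tomato fruit (Solanum lycopersicum) from 4 genotypes. These were the wild type, a line with the Aft (Anthocyanin fruit) allele, a line homozygous for atv (atroviolacea), and the double mutant that carries both. According to the labels, wild type and atv fruit held no significant anthocyanin, Aft fruit held a limited amount and double mutant fruit was strongly pigmented. Each genotype was represented by 2 biological replicates, each hybridised to its own array, so 8 arrays were compared and their number limits the precision. The median deposited intensity ranged from 514.5 in double mutant 2 to 755.4 in Aft mutant 2. Replicates correlated across probe sets with r between 0.977 in the atv mutant and 0.988 in the wild type. The atv mutant arrays stood apart from the rest, with a mean correlation of 0.904 with the wild type arrays, against 0.964 for the Aft mutant and 0.947 for the double mutant. The mean log2 difference between 3' and 5' control probe sets was 1.12 and 0.92 in the atv mutant, and 0.85 to 1.46 over the arrays of the other 3 genotypes. By the sample titles the wild type was cv. Ailsa Craig, and they name no cultivar for the mutant lines. Any difference in line background therefore goes with genotype in every comparison.

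The Aft mutant was compared with the wild type to find the transcripts that go with this allele alone. DFR, which encodes the dihydroflavonol reductase at the entry to anthocyanin synthesis, was near background in the wild type, at a log2 intensity of 2.02 ± 1.85 (SD, n = 2). It reached 10.67 ± 0.14 in the Aft mutant, at least 102-fold higher when values are floored at 16 (limma, adjusted p = 0.0032). CHS1, a chalcone synthase, rose by 2.97 on the log2 scale (SE 0.10, adjusted p = 0.00031), or 7.86-fold, and both Aft arrays lay above both wild type arrays for each of these genes. CHS2, another chalcone synthase, fell by 0.52 (adjusted p = 0.048), a call that ended on the deposited scale (adjusted p = 0.42). Further rises were the subtilisin-like protease sbt4a at 3.84 and the wound-inducible proteinase inhibitor PIIF (LOC543954) at 2.69. TLRP rose by 2.11, fsm1 by 1.84, Prg1 by 1.80 and the pathogenesis-related gene PR1b1 by 1.64. AGL11, a MADS-box gene at 1.37 in the wild type, and TPP3, at 3.91, rose at least 3.22-fold and at least 3.92-fold with values floored at 16.

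Genes of ripening and ethylene were among the largest falls in the Aft mutant. The ripening regulator RIN fell by 3.49 (SE 0.34, adjusted p = 0.0039), the ethylene-forming oxidases ACO6 and ACO4 fell by 3.57 and fell by 2.42, and the lipoxygenase LOXB fell by 2.48. Of the 39 ripening and ethylene genes measured, 3 rose, 7 fell and 29 did not pass the test; adjusted over the list alone, 5 rose and 9 fell. The list as a whole did not shift against other genes (camera adjusted p = 0.29), with a median near 0 and a mean of -0.28, while fry, a test against no change, called it down (adjusted p = 0.022). The invertase gene lin5 fell by 3.43 and the sucrose transporter SUT4 fell by 1.18. CEVI57 fell by 3.95 and WRKYIId-2 (LOC543855) fell by 2.63. One probe set of gts1 fell at least 7.84-fold with values floored at 16, and its other probe set did not pass (-1.41, adjusted p = 0.42). MT3 and TKR were called near background; floored at 16, MT3 (-0.73, adjusted p = 0.21) and TKR (-0.22, adjusted p = 0.69) were no longer called. Of 14 carotenoid genes, 3 fell and none rose, namely NSY (-2.04), NCED1 (-1.36) and Psy1 (-0.67) by the probe set used for the list, and the list shifted down (median -0.23, camera adjusted p = 0.015). The other probe sets of Psy1 disagreed, with a rise of 0.85 (adjusted p = 0.0079) and an uncalled 0.13 (adjusted p = 0.90), so its direction is open. Of 10 photosynthesis genes only the chlorophyll-binding protein gene CAB5 fell (-0.76), while the list shifted down (median -0.17, camera adjusted p = 0.0085). With an estimated correlation neither list shift held, at adjusted p = 0.44 for the carotenoid list and adjusted p = 0.22 for the photosynthesis list. The photosynthesis shift was also lost as deposited (adjusted p = 0.18) and the carotenoid shift without wild type 2 (adjusted p = 0.056).

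Over all probe sets, 530 of 9493 differed between the Aft mutant and the wild type, 264 higher and 266 lower, so 49.8% were higher. On the values as deposited 128 were higher and 162 lower, or 44.1% higher. The count was 207 without wild type 1, 205 without wild type 2, 312 without Aft mutant 1 and 332 without Aft mutant 2. Of 33 named genes called here, CHS2, TKR, NCED1, Psy1, CAB5, CCR1, P69A, PME2.1 and XTH6 were not called as deposited (adjusted p 0.055 to 0.47), and these 9 and AI were not called without at least 1 array (adjusted p 0.050 to 0.29).

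The atv mutant was compared with the wild type to ask what this allele changes in fruit without significant anthocyanin. CHS1 rose by 5.70 on the log2 scale (SE 0.10, adjusted p = 1.1e-05), or 52.0-fold as measured. DFR reached 7.70 ± 0.31 (SD, n = 2), at least 13.0-fold above the wild type with values floored at 16 (adjusted p = 0.0031). CHS2 differed by 0.19 and did not pass the test (adjusted p = 0.20). Genes of small heat shock proteins were among the largest rises of named genes. HSP17.4 went from 3.38 to 12.52, at least 366-fold with values floored at 16 (adjusted p = 0.00025). ER-SHSP rose by at least 6.83 on the log2 scale with the same floor, vis1 by 6.21, the mitochondrial MTSHP by 5.84 and HSP21 by 5.48. Of the 7 genes of the heat shock list, 6 rose and 1 fell (median 2.72, camera adjusted p = 0.00076; adjusted p = 0.19 with an estimated correlation); ER-SHSP and MTSHP were outside that list. The cold-response factor CBF1 rose by 5.50, from 4.95 and 5.08 on the wild type arrays to 10.46 and 10.58 on the atv mutant arrays. The shared estimate of its spread also holds 5.08 and 3.52 in the Aft mutant and 4.72 and 0.42 in the double mutant. With that spread, the call ended without any one of wild type 1, wild type 2, atv mutant 1 or atv mutant 2. All 4 cold and drought genes rose, the dehydrin TAS14 by 0.81 and the lipid transfer protein genes LE16 and TSW12 by 1.87 and 1.90 (median 1.89, camera adjusted p = 0.0078; adjusted p = 0.22 with an estimated correlation). The xyloglucan endotransglucosylases tXET-B2 and XTH3 rose by 6.02 and 5.32. One probe set of ca2 rose at least 3.91-fold with values floored at 16, and its other probe set (2.25) did not pass.

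Several defence genes that are abundant in the wild type were low in the atv mutant. NP24-I, an osmotin-like protein gene, fell by 8.75 (SE 0.08, adjusted p = 9.8e-07), ER1, which sits in the defence list among proteinase inhibitors, fell by 8.42, and the glucanase gene GluB fell by 6.98. The chitinase CHI9 fell by 4.28. The defence list as a whole held 5 rises, 8 falls and 9 genes that did not pass (median -0.29, camera adjusted p = 0.40; fry down, adjusted p = 0.00014). RIN fell at least 24.7-fold with values floored at 16, the ethylene response factor ERF4 fell by 3.95, ACO5 fell by 3.76 and the ethylene receptor ETR6 fell by 3.44, whereas ACO4 rose by 1.89. LePCL1 fell by 3.45 and TCP3 fell by 3.40. Of the 39 ripening and ethylene genes 7 rose and 22 fell (median -0.70, camera adjusted p = 0.018; adjusted p = 0.68 with an estimated correlation); adjusted over the list alone, 7 rose and 23 fell, and the shift was lost when all probe sets of the genes were used (adjusted p = 0.067). Carotenoid genes moved the other way, 11 of 14 rising and 1 falling, among them the lycopene cyclase CRTL-E-1 (2.52), the phytoene synthase PSY2 (2.33) and the hydroxylase CrtR-b1 (1.81). Their median was 0.92 (camera adjusted p = 3.6e-05; adjusted p = 0.21 with an estimated correlation), and 13 rose and 1 fell adjusted over the list alone. Of the 10 photosynthesis genes 7 rose, with CAB5 at 2.59, the protochlorophyllide reductase POR2 at 1.31 and plastocyanin, PETE, at 0.74 (median 0.58, camera adjusted p = 0.0005; adjusted p = 0.19 with an estimated correlation).

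Between the atv mutant and the wild type 3829 of 9493 probe sets differed, 1787 higher and 2042 lower (46.7% higher), against 1210 higher and 777 lower (60.9% higher) as deposited. Leaving out wild type 1 gave 2124 and leaving out wild type 2 gave 2236, and the atv mutant arrays are also the ones that stood apart in correlation. Of 51 named genes called, 6 were not called as deposited (adjusted p 0.052 to 0.15) and 6 not without at least 1 array (adjusted p 0.052 to 0.12).

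The double mutant was compared with the wild type to describe the strongly pigmented fruit. DFR reached 13.34 ± 0.06 (SD, n = 2), at least 649-fold above the wild type with values floored at 16 (adjusted p = 0.0011), and CHS1 rose by 5.42 (SE 0.10, adjusted p = 2.2e-05), or 42.7-fold as measured. CHS2 differed by -0.26 and did not pass (adjusted p = 0.15). Near background in the wild type, the peroxidase gene CEVI-1 rose at least 2.26-fold, AGL11 at least 2.35-fold and TPP3 at least 4.04-fold with values floored at 16. Prg1 rose by 3.28, sbt4a by 3.02, TLRP by 2.33 and PIIF by 2.11. ca2 was called near background and no longer with values floored at 16 (adjusted p = 1.0), and PIIF was not called without wild type 2 (adjusted p = 0.055). LOXB fell by 4.06 (SE 0.13, adjusted p = 0.00013), the lipoxygenase LOX1.1 fell by 2.81, the dioxygenase ODD fell by 4.25 and the alternative oxidase AOX1a fell by 2.76. CEVI57 fell by 4.51, WRKYIId-2 fell by 2.93 and lin5 fell by 2.91. With values floored at 16, gts1 fell at least 7.84-fold by 1 of its 2 probe sets (-1.62 and not called by the other), the expansin EXPA10 at least 8.35-fold and pip1 at least 8.49-fold. Without wild type 1 or wild type 2 the call of EXPA10 ended (adjusted p = 0.16 and 0.15), as did that of pip1 (adjusted p = 0.11 and 0.13). EXPA10 was also not called without Aft mutant 1 (adjusted p = 0.068) or Aft mutant 2 (adjusted p = 0.066), and pip1 not without Aft mutant 1 (adjusted p = 0.051).

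None of the 14 lists tested shifted against other genes in the double mutant by camera, while fry called 8 of them. Of the ripening and ethylene genes 7 rose and 8 fell (adjusted p = 0.49; fry down, adjusted p = 0.040), and of the 22 defence genes 3 rose and 6 fell (adjusted p = 0.44; fry down, adjusted p = 0.049), with the chitinase CHI3 at -1.92 and the lipoxygenase loxD at 1.90. Among carotenoid genes 2 rose and 2 fell (adjusted p = 0.49), with NSY at -1.87 and NCED1 at -1.88 among the falls and CRTL-E-1 (adjusted p = 0.12 as deposited) among the rises. In the heat shock list 2 of 7 genes fell, ER21 (-1.37; adjusted p = 0.066 without wild type 1) and HSP17-6 (-0.36; adjusted p = 0.22 as deposited), with a list adjusted p = 0.098 (fry down, adjusted p = 0.00027), and none of the photosynthesis genes passed the test (fry down, adjusted p = 0.011). In all, 1246 of 9493 probe sets differed, 702 higher and 544 lower (56.3% higher), against 175 higher and 267 lower (39.6% higher) as deposited. The count was 361 without wild type 1, 355 without wild type 2, 582 without double mutant 1, 430 without double mutant 2, 2211 without atv mutant 1 and 2197 without atv mutant 2, and 2269 with both atv mutant arrays left out, a setting chosen after seeing the data. Of 40 named genes called, 8 were not called as deposited (adjusted p 0.053 to 0.22) and 10 not without at least 1 array (adjusted p 0.050 to 0.25).

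**Figure D1:**
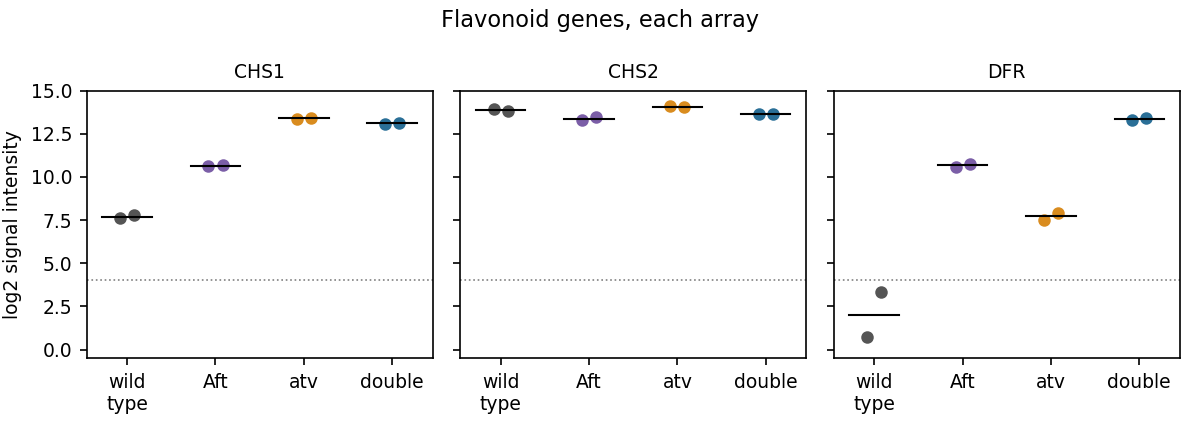
Log2 signal intensity of CHS1, CHS2 and DFR on each of the 8 arrays (points, 2 per genotype) with the genotype mean (line); the dotted line marks the filter at log2 4. CHS1 means were 7.68 in the wild type, 10.66 in the Aft mutant, 13.38 in the atv mutant and 13.10 in the double mutant, while DFR was highest in the double mutant at 13.34.

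The double mutant was compared with the Aft mutant to see what atv adds in an Aft background. CHS1 rose by a further 2.44 (SE 0.10, adjusted p = 0.00057), or 5.44-fold as measured. DFR was 2.67 higher (SE 0.79) and did not pass the test (limma, adjusted p = 0.12, or 0.0012 with values floored at 16). It read 10.573 and 10.771 on the Aft mutant arrays and 13.297 and 13.385 on the double mutant arrays. The shared estimate of its spread also holds 0.711 and 3.334 in the wild type, near background and outside this comparison. CHS2 differed by 0.26 (adjusted p = 0.19). ACO4 rose by 2.27, TSI-1 by 2.40, BR1 by 1.77, ARPI by 1.75, the NADPH oxidase RBOH1 by 1.73 and ETR6 by 1.72. With values floored at 16, MT3 rose at least 2.65-fold and the ribonuclease RNALE at least 3.19-fold, while TKR (adjusted p = 0.90) and vis1 (-0.78, adjusted p = 0.079) were no longer called. ODD fell by 5.19, AOX1a fell by 2.92, CHI3 fell by 2.39, the gibberellin oxidase 20ox-3 fell by 1.65, LOXB fell by 1.58, the galactosidase TBG1 fell by 1.47, LOX1.1 fell by 1.20 and THT7-1 fell by 1.18. EXPA6 fell by 1.24 by 1 probe set and was at 0.23 by the other. Of the heat shock list 3 genes fell and 4 did not pass (median -0.45, camera adjusted p = 0.0043; adjusted p = 0.22 with an estimated correlation). Of the 4 cold and drought genes 3 rose, TSW12 by 1.52, TAS14 by 1.21 and LE16 by 0.99 (camera adjusted p = 0.014; adjusted p = 0.23 with an estimated correlation), a shift that was lost without double mutant 1 (adjusted p = 0.14). TAS14 had been at -1.30 in the Aft mutant against the wild type (limma, adjusted p = 0.0038). In the double mutant it stood at 9.37, near the wild type level of 9.46. LE16 (13.08 against 11.91) and TSW12 (9.69 against 8.73) stood above the wild type. Of 22 defence genes 4 fell and 1 rose (median -0.29, camera adjusted p = 0.041, or 0.68 with an estimated correlation), and this shift was lost as deposited (adjusted p = 0.13). With all arrays this comparison gave the fewest calls, 389 of 9493, with 239 higher and 150 lower (61.4% higher, but 37.4% without double mutant 1), against 40 higher and 36 lower (52.6% higher) as deposited. It also moved with single arrays: 153 without wild type 1, 141 without wild type 2, 82 without Aft mutant 1, 251 without Aft mutant 2, 155 without double mutant 1, 77 without double mutant 2, 878 without atv mutant 1 and 862 without atv mutant 2, and 903 with both atv mutant arrays left out, more than the 576 then called between Aft mutant and wild type. Of the 33 named genes called, 23 were not called as deposited (adjusted p 0.051 to 0.35) and 21 not without at least 1 array (adjusted p 0.050 to 0.26), while CHS1, ACO4, MT3, ODD, AOX1a, CHI3, LOXB and TBG1 were called in all of these settings.

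The double mutant was compared with the atv mutant to see what Aft adds in an atv background. DFR rose by 5.64 (SE 0.79, adjusted p = 0.0029), and CHS1 differed by -0.28 (SE 0.10) and did not pass (adjusted p = 0.073). In the double mutant both were near the top of the signal range, at 13.34 and 13.10, where a rise can be compressed, so the sizes of these changes cannot be set against each other. CHS2 fell by 0.44 (adjusted p = 0.018), a call that ended on the deposited scale (adjusted p = 0.096). Genes that had fallen in the atv mutant were higher in the double mutant, NP24-I by 8.19 (SE 0.08, adjusted p = 1.4e-06), ER1 by 7.90, GluB by 6.24, ACO5 by 5.29, ERF4 by 4.78 and ETR6 by 4.60. The same atv mutant arrays enter this comparison and the interaction with the opposite sign to that in atv mutant against wild type. Reversals of genes and lists between these comparisons are therefore not independent evidence that Aft undoes a change made by atv. The protease gene sbt4a rose by 4.67 and, with values floored at 16, AGL11 at least 2.35-fold and CEVI-1 at least 2.26-fold. HSP17.4 fell at least 262-fold, ER-SHSP fell by at least 6.95 on the log2 scale, vis1 at least 84.0-fold and CBF1 at least 71.5-fold, while MTSHP fell by 6.07 and HSP21 fell by 5.94. CEVI57 fell by 5.17, tXET-B2 fell by 4.75, the malate dehydrogenase chMDH fell by 4.66 and ER24 fell by 4.52. Of the heat shock list 6 of 7 genes fell (median -3.43, camera adjusted p = 0.0003; adjusted p = 0.19 with an estimated correlation). Carotenoid genes fell in 12 of 14 cases (median -1.05, camera adjusted p = 6e-06; adjusted p = 0.19 with an estimated correlation) and photosynthesis genes in 9 of 10 (median -0.58, camera adjusted p = 0.00014; adjusted p = 0.19 with an estimated correlation). All 4 cold and drought genes fell (median -0.92, camera adjusted p = 0.018; adjusted p = 0.25 with an estimated correlation), and of the ripening and ethylene genes 20 rose and 9 fell (camera adjusted p = 0.29; fry up, adjusted p = 0.011). The total was 4178 of 9493 probe sets, 2347 higher and 1831 lower (56.2% higher), against 698 higher and 1554 lower (31.0% higher) as deposited, and 2584 without double mutant 2. Of 50 named genes called, 8 were not called as deposited (adjusted p 0.060 to 0.82) and 5 not without at least 1 array (adjusted p 0.052 to 0.15), CHS2, COP1, HY5, RPL37 and SUT4.

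**Figure D2:**
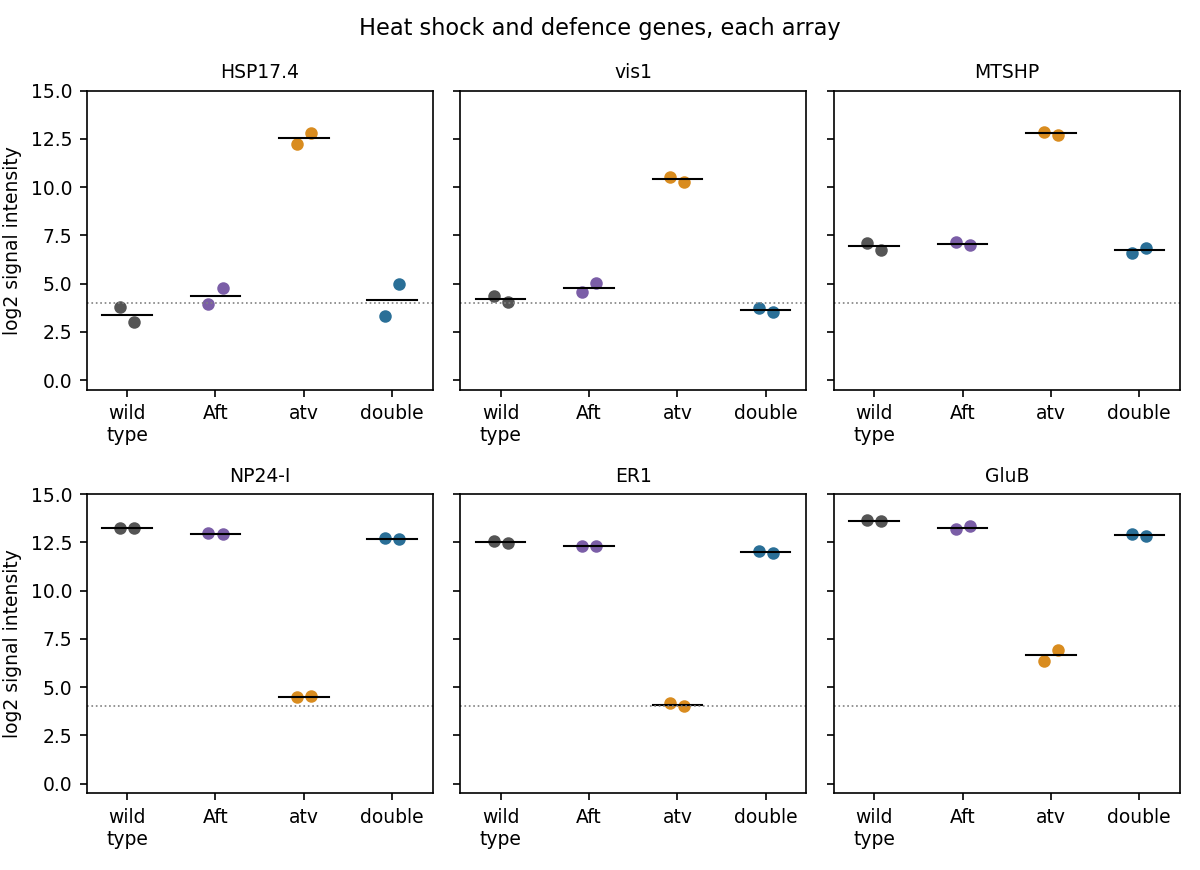
Log2 signal intensity of 3 heat shock genes (upper panels) and 3 defence genes (lower panels) on each of the 8 arrays (points, 2 per genotype) with the genotype mean (line); the dotted line marks the filter at log2 4. HSP17.4 stood at 12.52 in the atv mutant against 3.38 in the wild type, and NP24-I at 4.50 against 13.25.

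The interaction asked whether the effects of both alleles add up on the log2 scale, as the difference of double mutant minus Aft mutant and atv mutant minus wild type. The CHS1 signal rose by less with atv when Aft was present (interaction -3.26, SE 0.15, adjusted p = 0.00023), which compression near the top of the range could also produce. DFR, near background in the wild type, gave -3.01 (SE 1.12) and did not pass (adjusted p = 0.11); with values floored at 16 it gave -1.04 (adjusted p = 0.020), so its size hangs on the floor and, at the level of DFR in the double mutant, on compression as well. Heat shock genes were among the most negative interactions of named genes, with a list median of -3.17 (camera adjusted p = 7.7e-05; adjusted p = 0.19 with an estimated correlation), and NP24-I (8.48), ER1 (8.11) and GluB (6.60) were among the most positive of named genes, with sizes as measured, since NP24-I and GluB lay near the top of the range in the wild type. Carotenoid (median -0.80, camera adjusted p = 0.00028; adjusted p = 0.22 with an estimated correlation) and photosynthesis genes (median -0.43, camera adjusted p = 0.0011; adjusted p = 0.19 with an estimated correlation) shifted down, and ripening and ethylene genes up (median 0.41, camera adjusted p = 0.024; adjusted p = 0.68 with an estimated correlation). The ripening shift was lost without wild type 1 (adjusted p = 0.062), Aft mutant 2 (adjusted p = 0.082) or double mutant 2 (adjusted p = 0.065). In all 2293 of 9493 probe sets had an interaction, 1186 positive and 1107 negative (51.7% positive), against 271 and 601 (31.1% positive) as deposited. The count was 1172 without wild type 1, 1192 without wild type 2, 1464 without double mutant 1 and 1312 without double mutant 2. Of 44 named genes called, 11 were not called as deposited (adjusted p 0.060 to 0.46) and 9 not without at least 1 array (adjusted p 0.052 to 0.16).

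**Figure D3:**
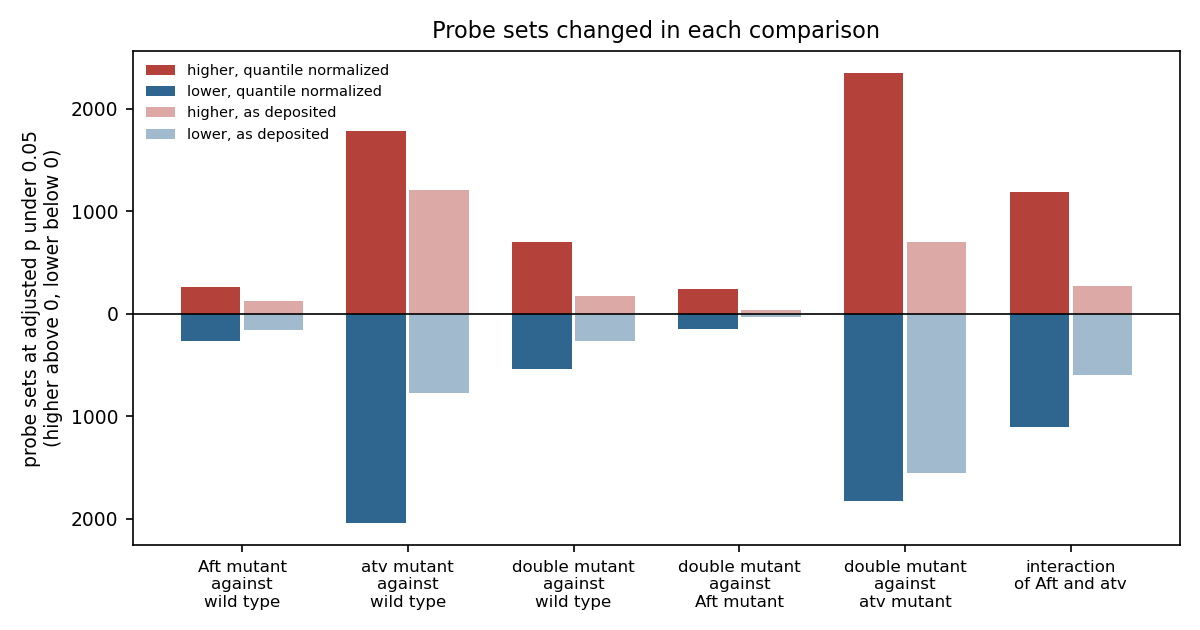
Number of probe sets at adjusted p under 0.05 in each of the 6 comparisons, higher above and lower below the zero line, on quantile-normalized values (dark) and on the values as deposited (light). The largest count was 4178, between double and atv mutant, and the smallest 389, between double and Aft mutant.

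The log2 changes of the mutants were also compared with each other across probe sets, which are not independent replicates. All 3 comparisons with the wild type use the same 2 wild type arrays, so part of any excess may come from those shared controls; with no effects simulated, shared arrays alone gave a correlation of 0.50. Changes in the Aft and double mutants correlated at 0.65, with 210 probe sets higher in both (19.5 if independent) and 171 lower in both (15.2 if independent). The Aft and atv mutants gave 0.20, and the atv and double mutants 0.30. Neither value means less sharing than shared arrays alone give, as covariances were 0.15 and 0.28, against 0.05 simulated without effects. Aft and atv had 237 probe sets called the same way (106.9 if independent) and 141 in opposite directions (106.9 if independent). For atv and double these were 541 (249.2 if independent) and 261 (253.4 if independent). In all 3 mutants, 113 probe sets were higher than in the wild type, CHS1, DFR, PR1b1, Prg1, TPP3 and tXET-B2 among them, and 65 were lower, among them RIN, LOXB, lin5, SUT4, NCED1 and EXPA6. Where no array is shared, the change from wild type to atv mutant and the change from Aft to double mutant correlated at 0.18, and 4.83% of the probe sets called in the first were called the same way in the second; 185 were called the same way in both (77.3 if independent) and 83 in opposite directions (79.6 if independent). The change from wild type to Aft mutant and the change from atv to double mutant, which share no array either, correlated at 0.26. Of the probe sets called in the first of these, 58.7% were called the same way in the second, with 311 called the same way in both (117 if independent) and 120 in opposite directions (117 if independent).

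**Figure D4:**
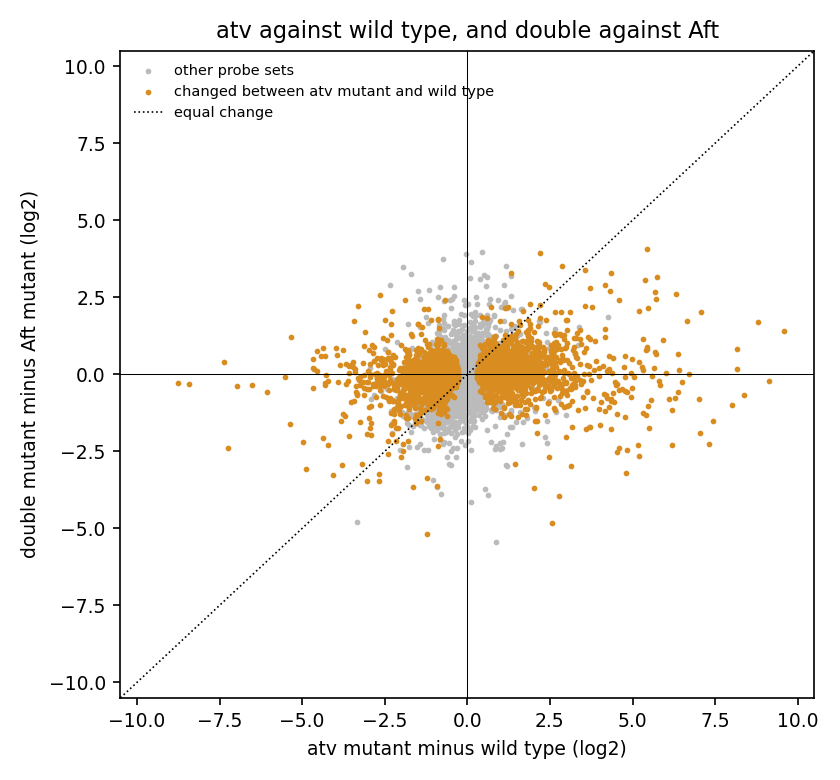
Log2 change from Aft to double mutant (vertical axis) against the change from wild type to atv mutant (horizontal axis), 1 point per probe set; orange points are the 3829 called between atv mutant and wild type and the dotted line marks equal change. The slope over the orange points was 0.073.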

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

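The results below differ between fruit with and without Aft under the same change, by the interaction test. Of the tests of explanations, only those of scanner range and of chance values in the wild type arrays were fixed before their results were seen; the others were chosen afterwards.

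In all, 2293 probe sets had an interaction. Of 7 heat shock genes 6 rose and 1 fell with atv alone (list median 2.72), and none rose and 3 fell with atv in the Aft background (-0.45), an interaction of -3.17; these list shifts were lost with an estimated correlation (camera adjusted p = 0.19, 0.22 and 0.19). HSP17.4 gave -9.35, ER-SHSP -8.96, vis1 -7.37, HSP21 -6.51 and MTSHP -6.19. With values floored at 16 these were -8.43 for HSP17.4, -6.83 for ER-SHSP and -6.99 for vis1. In the opposite direction NP24-I gave 8.48, ER1 8.11 and GluB 6.60. Quantile normalization is argued against as the whole source, since on the deposited scale the heat shock median, taken per array, was 2.01 higher in the atv mutant (SE 0.20 between arrays), and 5 of its 7 members were called; the error was chosen after this value was seen, and with the spread among members the test would not decide. What may have set the atv mutant fruit apart, namely genotype, harvest, handling, stage or line background, cannot be told apart, because all of these go with the same 2 arrays. Their highest mean correlation with another genotype was 0.904 against a lowest of 0.947 between the others. An allele effect alike in both backgrounds stays open for the same reason: over the 3829 probe sets called between atv mutant and wild type the slope of the change from Aft to double mutant was 0.073 (0.045 to 0.13 without single arrays), which a difference of those 2 arrays alone could give.

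CHS1 had an interaction of -3.26: it stood at 13.38 in the atv mutant, without significant anthocyanin by the labels, and at 13.10 in the double mutant, while DFR was higher in the double mutant. Signal near the top of the range stays open: 0.219% of probe sets were brighter than CHS1 by over 0.5 on the log2 scale in the atv mutant, so a further rise could have been compressed. Compression could hide a rise but would not by itself lower the signal. From atv to double mutant CHS1 differed by -0.28 (SE 0.10), with both double mutant arrays below both atv mutant arrays, though this did not pass the test. An Aft effect on CHS1 in the atv background like that in the wild type background (2.97) was thus not seen. Hidden by compression, it is argued against only weakly. Transcripts of CHS2 binding the CHS1 probe set are argued against in the double mutant, where CHS2 was at -0.44 (SE 0.10) against the atv mutant and -0.26 against the wild type, although a rise like that of CHS1 would have brought it at least to its atv level. The argument is limited, since the -0.44 was not called on the deposited scale and the -0.26 did not pass the test. In the wild type CHS2 read 13.88 and CHS1 only 7.68, so such binding in the atv mutant would need a large further rise of CHS2. This stays open, as CHS2, at 14.07 in the atv mutant, was brighter than CHS1. Its change of 0.19 from the wild type cannot show a compressed rise.

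RIN fell in all 3 mutants and had an interaction of 6.55 (5.85 with values floored at 16). It was among 65 probe sets lower in all 3 mutants than in the wild type, 19 without wild type 1 and 20 without wild type 2. Chance values of the shared wild type arrays are argued against only for the probe sets so called without 1 wild type array. Of these, 100% had the left-out array above all 6 mutant arrays. The 14.3% due for exchangeable arrays is no exact reference, since these probe sets were chosen for low mutant arrays. The 65 as a whole were not tested this way. This test replaced an earlier one, in which 100 simulations without effects gave at most 0 probe sets lower in all 3 mutants. Wild type fruit further toward ripening than the mutants could not be decided. Against other genes, the ripening and ethylene list fell by camera in 1 of the 3 mutants with the preset correlation and in none with an estimated one. Fry, a test against no change, called it down in all 3 (adjusted p = 0.022, 0.0031 and 0.040). Of its members, 3 were lower and 1 higher in all 3. Stage, harvest and line background of the wild type may be involved and go with genotype here.

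Other genes with an interaction were ETR6 at 5.16, ERF4 at 4.59, ACO5 at 4.54, MT3 at 4.50 (2.13 with values floored at 16), ICL (LOC544276) at 4.46 and TSI-1 at 4.27. In the negative direction CBF1 gave -7.23 (-5.68 floored), tXET-B2 -5.97, GLB2 -5.43 (-1.10 floored), PIIF (LOC543954) -5.42 and XTH3 -5.19; CBF1 was not called without wild type 1 (adjusted p = 0.12), wild type 2 (adjusted p = 0.12), Aft mutant 1 (adjusted p = 0.12), Aft mutant 2 (adjusted p = 0.071), atv mutant 1 (adjusted p = 0.090) or atv mutant 2 (adjusted p = 0.084), nor GLB2 without wild type 2 (adjusted p = 0.058). The carotenoid list gave a median of -0.80, the photosynthesis list -0.43 and the ripening and ethylene list 0.41. These shifts too were lost with an estimated correlation (camera adjusted p = 0.22, 0.19 and 0.68).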

How the results depend on the processing

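Of 251 called gene results and 18 called list shifts none reversed direction under the alternatives tried. Of the gene results 172 were called in every alternative that tested them, and 186 on the values as deposited; the stricter filter, probe set types and fits to fewer groups were not run for single genes. None of the list shifts held with an estimated correlation. The deposited scale lowered the counts to 290 (Aft mutant against wild type), 1987 (atv mutant against wild type), 442 (double mutant against wild type), 76 (double against Aft mutant), 2252 (double against atv mutant) and 872 (interaction). Of the calls on normalized values, 268, 1943, 428, 75, 2167 and 849 in that order were also made in the same direction as deposited and none in the opposite one; the median of all probe sets moved by -0.06, 0.05, -0.17, -0.11, -0.23 and -0.16. Between double and Aft mutant, an intensity trend gave 698, a floor of 16 gave 584, a fit to both groups alone 224 and a fit without the atv mutant arrays 903. Between double mutant and wild type these gave 1984 (trend), 2530 (both groups alone) and 2269 (without the atv mutant arrays). The floor of 16 and the fit without atv mutant arrays were chosen after seeing the data. Beyond the smaller spread without the atv mutant arrays and the smaller number of arrays, the cause was not tested.

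Leaving out 1 array at a time, with the lone array of a genotype assumed to vary like the others, gave 205 to 562 (Aft mutant against wild type), 2124 to 3825 (atv mutant against wild type), 355 to 2211 (double mutant against wild type), 77 to 878 (double against Aft mutant), 2584 to 4237 (double against atv mutant) and 1172 to 2606 (interaction). Replicate numbers did not pair the arrays: deviations of same-numbered replicates correlated at -0.04 to 0.18 across probe sets, and a replicate block gave 456, 3765, 1364, 356, 4111 and 2170. Among probe sets called in neither mutant, the correlation of changes was 0.154 for Aft and atv, 0.411 for Aft and double, and 0.330 for atv and double. Signal over background limits the low end: at least 7.29% of probe sets on each array lay under 16 as deposited, and the 545 that failed the filter gave no test.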

Other observations

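Cell wall genes changed in every mutant without a shift of the list against other genes by camera, though fry called the list up in the atv mutant (adjusted p = 0.0084). Of 30 genes, 6 rose and 2 fell in the Aft mutant (camera adjusted p = 0.51), 9 rose and 8 fell in the atv mutant (adjusted p = 0.40) and 6 rose and 5 fell in the double mutant (adjusted p = 0.86). The expansin EXPA6 fell in all 3 by 1 probe set, at -1.39 in the Aft and -2.63 in the double mutant (-2.08 and -1.85 by the other, not called). EXP1 rose in all 3, from 4.70 in the wild type to 5.35 in the Aft, 5.89 in the atv (a rise of 1.19) and 5.39 in the double mutant. PME2.1, a pectin methylesterase, was called lower in all 3, at -0.61 in the Aft and -1.05 in the double mutant. In the atv mutant it stood at 11.99, against 12.59 in the wild type. Sugar genes were mixed: lin5 fell in all 3 mutants, while in the atv mutant LIN8 rose by 4.26 and the starch gene AGPL3 by 2.46, and the vacuolar invertase AI was at -1.01 in the Aft and -1.15 in the atv mutant. The sugar and starch list did not shift against other genes (camera adjusted p = 0.45, 0.86 and 0.57 for Aft, atv and double mutant), while fry called it down in the Aft (adjusted p = 0.025) and double mutants (adjusted p = 0.034). The sucrose transporter SUT4, one of 2 vascular markers, fell in all 3 mutants (-1.18, -1.66 and -1.16), and SUT2 in the atv mutant (-0.65; adjusted p = 0.091 as deposited).

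Several hormone and light genes were called in the atv mutant. IAA3 rose there by 1.85 and IAA7 by 1.31, and ARF3 was at -0.69 (1.23, 0.76 and -0.32 by their other probe sets), a call that ended for ARF3 without wild type 1 (adjusted p = 0.057). The auxin list did not shift by camera (adjusted p = 0.29, 0.58 and 0.90), while fry called it down in the Aft mutant (adjusted p = 0.041). The gibberellin oxidase 20ox-3 fell in the atv (-2.30) and double mutants (-2.02), and the DELLA gene GAI in the atv mutant (-1.15); the gibberellin list did not shift by camera (adjusted p = 0.88, 0.76 and 0.66), while fry called it down in the atv (adjusted p = 0.0094) and double mutants (adjusted p = 0.043). HY5, a light-response factor, rose by 0.58 in the atv mutant and CRY2 and COP1 were at -1.05 and -0.68, calls that ended as deposited for HY5 (adjusted p = 0.13) and COP1 (adjusted p = 0.059); the light signalling list did not shift by camera (adjusted p = 0.43, 0.97 and 0.73). Among 5 phenylpropanoid genes THT7-8 rose at least 4.44-fold in the atv mutant with values floored at 16 and THT7-1 was at -1.97 in the double mutant (list by camera, adjusted p = 0.20, 0.88 and 0.37; by fry down in the Aft and double mutants, adjusted p = 0.040 in both). No ribosomal protein gene was called in any mutant against the wild type (list by camera, adjusted p = 0.57, 0.40 and 0.88; by fry down in the atv mutant, adjusted p = 0.0028). Of 4 reference genes tubulin, TUB, was at -0.41 in the atv mutant, a call that ended as deposited (adjusted p = 0.15; list by camera, adjusted p = 0.94, 0.57 and 0.90; by fry down in the atv mutant, adjusted p = 0.029). The histone gene H1 was at -0.50 in the atv mutant (adjusted p = 0.026; 0.13 as deposited), the trichome marker MTS1 was not called (-0.50, adjusted p = 0.74 in the atv mutant), the epidermis marker LE16 rose in the atv (1.87) and double mutants (1.16; adjusted p = 0.067 as deposited) while ltpg1 did not pass, and the 1 seed marker failed the filter.

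ANT1, a MYB candidate at the Aft locus and the 1 regulator gene with a named probe set, failed the filter. Its mean log2 levels were 1.02 in the wild type, 2.24 in the Aft mutant, 0.92 in the atv mutant and 1.13 in the double mutant. Other candidate genes were not matched to a probe set by symbol, so their transcripts were not assessed. Among probe sets without a gene name, one was near background in the wild type (1.57) and the atv mutant (0.35) and reached 11.32 in the Aft and 11.34 in the double mutant, at least 160-fold and at least 162-fold above the wild type with values floored at 16. Another rose in all 3 mutants, at least 33.0-fold in the Aft, at least 16.1-fold in the atv and at least 200-fold in the double mutant. One stood at 8.83 in the wild type and was near background in all 3 mutants, a fall of at least 28.4-fold, and another fell at least 180-fold in the Aft and at least 146-fold in the double mutant. These were chosen after their values were seen. The mutant lines may carry introgressed segments. Whether these changes go with such segments rather than with the alleles was not tested, as chromosomal positions were not used.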
